A study of Drosophila melanogaster with 2 samples.

How the data were processed

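ChIP-seq with an antibody against GFP was done on whole Drosophila melanogaster embryos aged 0 to 18 h that expressed a fusion of wor with enhanced GFP, in 2 biological replicates that form 1 group. Per the labels, chromatin was fragmented by sonication, the fragments had a size range of 200 to 800 bp, and the assembly was dm6. The deposited files were 4 thresholded and 4 ranked peak lists, 1 of each kind for each replicate and 2 of each kind made from both replicates. The irreproducible discovery rate (IDR) compares the ranks of peaks between sets of peaks and gives each peak a measure of reproducibility. Per the deposited sample notes, each list was derived from filtered alignments and further inputs that the notes do not describe. The aligner, the peak caller and their versions are not given in the sources used here. Which control library the authors used is not settled by these sources, and no control library is analysed here, so no value below has been set against a control immunoprecipitation.

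The score of each peak in the deposited lists is a whole number from the IDR step that is capped at its upper end. The signal of each peak is the authors' own value per peak and is not scaled between lists. Signals were used to describe, rank or filter peaks within 1 list, and between lists only in the correlation of the replicates. The deposited ranked lists also give the −log10 of the global IDR per peak, and each thresholded list holds only peaks of its ranked list with a value of at least 2, an IDR of at most 0.01. The thresholded lists lack 54 to 105 peaks of the ranked lists that meet this limit, and the reason is not given in the sources used here. The summit of each peak is deposited as a distance in bp from the start of the peak. The 2 ranked lists made from both replicates carry 4 further columns of values per input, which were not used here. Coordinates are printed with the first base of an arm counted as 1, start and end included.

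The conservative list was the main peak set. Peaks on arms 2L, 2R, 3L, 3R, 4, X and Y were analysed, and peaks on unplaced contigs, 19 in the conservative list, were counted only. Genes and transcripts were those of Ensembl release 115 (BDGP6 annotation 54) with the sequence of RefSeq Release 6, whose arm lengths were checked against the largest coordinates of the lists. The depth per library was not given in the files, so the precision of shares is stated as 95% Wilson intervals over peaks, which cover counting error only. For a count of 0 the limit given is 3 counts of the total.

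Peaks of the replicates were shared if they overlapped by at least 1 bp. This was compared with 1000 random placements of the replicate 2 peaks on their own arms (one-sided). Signal was correlated over conservative peaks with a summit within 100 bp in both replicates' ranked lists, with 100000 permutations of the pairing. Summits within 500 bp of an annotated transcript start were counted and compared with 1000 random placements (two-sided) and with the ranked peaks outside the conservative list. Peaks per arm were tested with exact binomial tests against the arm's share of bases. Motifs were searched on both strands within 50 bp of the summit and in a window of the same width centred 500 bp downstream, that is at the higher coordinate. Exact sign tests were run over peaks with the motif in 1 of the windows. The 11 motifs were the Snail-type E-box CAGGTG, Zelda-type CAGGTAG, Ase/Ac-type CAGCTG, Twist-type CATATG, Myc-type CACGTG, GAGA GAGAGAG, DRE TATCGATA, M1BP-type GGTCACACT, Su(H)-type GTGGGAA, Grh-type AACCGGTT and the reversed Snail-type control GTGGAC. The 761 strongest and the 761 weakest peaks of the list were compared by Fisher's exact test.

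Each peak was given to the protein-coding gene with the nearest annotated transcript start. For each of 18 gene lists, the number of member genes with a conservative peak was compared with 100000 random draws of as many genes matched on decile of territory length, a permutation of list membership, two-sided. The territory of a gene reaches midway to the neighbouring starts. P-values were adjusted by Benjamini and Hochberg over lists, over motifs and over arms, with a threshold of 0.05. The lists were the Snail family, neuroblast factors, temporal series, asymmetric division, cell cycle, neuron differentiation, motor and interneuron factors, glia, mesoderm and muscle, neuroectoderm genes repressed by Snail, Notch pathway, gap, pair-rule and segment polarity, Hox, trachea, endoderm and fat body, housekeeping, chemosensory receptors and eggshell and yolk. Members were matched by symbol or recorded synonym and 0 were unmatched. Delta is the current symbol of the member listed as Dl. Some genes are in several lists.

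The tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. The rule names wor in every list, the genes of the 20 conservative peaks with the highest signal, the 10 genes with the most peaks (ties ordered by strongest signal), and for each gene list up to 4 members with the strongest peaks and up to 2 members without a peak, taken in alphabetical order. For 1 of the genes that this rule takes, the result is not reported here. GC profiles, the ranges along the ranked list and the counts of peaks near Snail-family genes were added after the data were seen.

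Alternatives fixed beforehand were the second list of both replicates, the stronger part of the list by signal, each replicate's own list in place of the conservative one, other overlap rules, other distances and windows, other motif backgrounds including shuffles that keep dinucleotides, other assignments of peaks to genes, no matching on territory length, and distal summits only. Alternatives added after seeing the data left out peaks that overlap a stronger peak of the same list, matched draws also on the lowest GC content near a gene's starts in 5 classes, used ranked peaks outside the conservative list as the peak set for lists and motifs, and took the expected share per arm from ranked peaks.

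The steps were tested on simulated data. Of 200 simulated lists of 20 genes with unchanged binding, 0.5% had an unadjusted p under 0.05, and of 200 with binding raised 3-fold, 96.5% did. All were drawn from genes with large territories, so the 96.5% does not carry over to shorter lists, smaller territories or smaller changes. Calls in the text use adjusted p, which these simulations did not apply for lists and motifs. The motif test gave an unadjusted p under 0.05 in 5% of runs with no motif planted and in 100% of runs with the motif planted in 10% of windows. Its windows were random genome windows, so the 5% does not carry over to summits whose GC content differs from that of their background. The 100% does not carry over to smaller excesses. The overlap step found 50.4% of peaks shared when 50% were planted, and the correlation step returned 0.801 when 0.8 was planted. The arm test, with adjusted p, called an arm in 3.5% of null draws. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.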

Results

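Worniu, encoded by wor, is a zinc finger transcription factor of the Snail family that is expressed in neuroblasts, the neural stem cells of the fly embryo. Chromatin immunoprecipitation and sequencing (ChIP-seq) was done with an antibody against GFP on Drosophila melanogaster embryos aged 0 to 18 h that carried a fusion of wor with enhanced GFP. Whole embryos were used, so the libraries held chromatin of all embryonic tissues. There was 1 group with 2 biological replicates and no second condition. The deposited files gave peak positions on the dm6 assembly with a signal and a reproducibility score per peak. The number of reads per library was not given in the files, so the depth is unknown. The main peak set was the conservative list, made from both replicates and filtered by the irreproducible discovery rate (IDR), with 3064 peaks of median width 364 bp. Of these, 3045 lay on the 7 chromosome arms and were used below. The thresholded lists of the single replicates held 2302 peaks for replicate 1 and 1801 for replicate 2. A second list made from both replicates held 3081 peaks. With 1 group of 2 replicates no test across embryos was possible, and p-values below are over peaks or genes of this peak set. Intervals of shares are 95% Wilson intervals and cover counting error only.

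The comparison of the replicates asked whether the same regions were recovered in both. The strongest regions were shared, and all 20 of the highest peaks of the conservative list, from the intron of CG11050 to that of Hr3, were in the thresholded lists of both replicates. Of the 2266 peaks of replicate 1 on the arms, 1549 (68.4%, interval 66.4 to 70.2) were overlapped by a peak of replicate 2. In 1000 random placements of the replicate 2 peaks the mean was 0.846% and the highest was 1.46%, giving a one-sided p of 0.001, the smallest the placements can give. In the other direction 85.2% of the replicate 2 peaks were overlapped by replicate 1. Of the 717 replicate 1 peaks outside the thresholded list of replicate 2, 672 (93.7%) lay in the longer ranked list of replicate 2. Signal was correlated over the 2650 of 3045 conservative peaks with a summit match in both ranked lists. Spearman's rho was 0.827 and Pearson's r on log2 signal was 0.90, each with a permutation p of 1e-05, the smallest 100000 permutations can give. Without the 2 peaks farthest from the median, rho was 0.827 and r was 0.898. These correlations are across peaks, which are not independent replicates. The IDR step and the match in both lists keep peaks that are alike in the replicates, so the values describe the selected peaks and do not test reproducibility.

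The strongest peaks lay mostly near transcript starts, at genes of varied function. The highest peak, at 2L 6612535 to 6612881, lay in an intron of CG11050 (FBgn0031836), 1019 bp from the start of that gene, with a signal of 1620. The next was at X 2703710 to 2704054, 44 bp upstream of Ugalt (FBgn0024994), which encodes a nucleotide-sugar transporter, with a signal of 1463. A peak at 3L 19590453 to 19590782 lay 94 bp upstream of CG14100 (FBgn0036889), with a signal of 1408. HmgZ, which encodes an HMG-box chromatin protein, followed with 1404, in an intron at 2R 21703226 to 21703652. ph-p, a Polycomb group gene, had a peak of 1280 in its intron at X 2137185 to 2137525. Chro, whose chromodomain protein marks the interbands of polytene chromosomes, had one of 1237 in its 5' UTR at 3L 22878739 to 22879065. Trl, which encodes GAGA factor, had an intronic peak of 972. The transcription factor gene Adf1 had one of 1050, and the nuclear receptor gene Hr3 one of 945. mRpL41, a mitochondrial ribosomal protein gene, had a peak of 1226 located 142 bp upstream of its start. PNPase, a mitochondrial exoribonuclease gene, had one of 959 in its 5' UTR. The others of the 20 strongest peaks were nearest to CG13323, px, Tcs5, CG18549, CG5611, Fkbp14, Tina-1, Art3 and CG4004, with signals from 957.9 to 1256. Of the 20 summits, 14 lay within 500 bp of a transcript start. None of the 20 had the Snail-type hexamer CAGGTG within 50 bp of its summit. Signal is the authors' own value per peak and, apart from the correlation of the replicates, is used here only to rank and describe peaks within a list.

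Nearest-start assignment gave the conservative peaks to 2031 of 13968 protein-coding genes, of which 1443 had 1 peak and 224 had at least 3. The gene with the most peaks was CG43245 (3L 10771925 to 10773399), with 11. hng3 had 10. CHES-1-like, a forkhead gene, shn, a zinc finger gene of the BMP pathway, shep, an RNA-binding protein gene, CG7560 and CG13898 had 9 each. Raf, the MAP kinase kinase kinase gene, and dnc, the cAMP phosphodiesterase gene, were among 4 genes with 8. Several of these have large territories, 122 kb for shep and 124 kb for dnc, and such genes collect more peaks under this rule. Without peaks that overlap a stronger peak the counts were 10 for CG43245, 9 for CHES-1-like, 8 for hng3, shep and CG13898, 7 for shn, Raf and dnc, and 6 for CG7560.

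The tagged gene itself was recovered at moderate strength. The conservative peak nearest to wor (FBgn0001983, 2L 15423297 to 15425580) lay at 2L 15426813 to 15427176, in intergenic sequence 1415 bp upstream of its start. Its signal was 113.7, rank 1546 of 3045. A weaker overlapping peak stood beside it with a signal of 22.3. Farther upstream lay conservative peaks of 82.6 (2L 15429571 to 15429934) and 263.0 (2L 15436052 to 15436142). The nearest-start rule did not give these to wor. Neither replicate's thresholded list held a wor peak. Their ranked lists held one at the same place, with signals of 53.7 in replicate 1 and 56.1 in replicate 2. Of the other Snail-family genes, sna, which directs mesoderm formation, had a peak of 76.9 located 11681 bp from its start. scrt, expressed in neurons, had one of 74.0 located 275 bp upstream, and esg had none. These sna and scrt peaks were in neither replicate's thresholded list, and the sna peak had no summit match in the ranked list of replicate 2. With 3 of 4 members against 0.983 in matched draws, the family did not pass (adjusted permutation p = 0.266). Without replicate 2 the family had 0 members bound against 0.812 expected. Without replicate 1 it had 2 against 0.670, by peaks other than those named here.

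**Figure D1:**
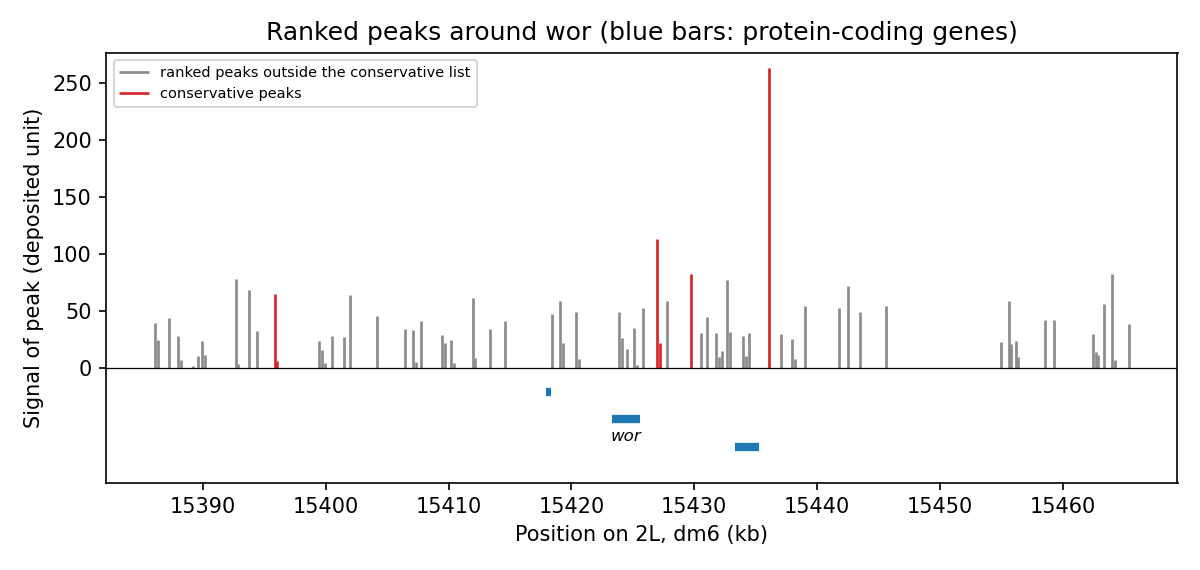
Peaks of the ranked list made from both replicates along 80 kb around wor on 2L (dm6), with position in kb on the x axis and the deposited signal of each peak at its summit on the y axis. Red lines are conservative peaks, grey lines are other ranked peaks and blue bars are protein-coding genes. The conservative peak nearest to wor stands at 113.7 and a stronger one farther upstream at 263.0.

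Gene lists asked which kinds of genes had a conservative peak more often than other genes with territories of like length, by permutation of list membership. Of the 18 lists, only the list of highly transcribed housekeeping genes was bound more often and only the chemosensory receptor list less often, in this setting. Ribosomal protein, actin, tubulin, Gapdh and related genes had 28 of 90 bound against 10.1 expected. The raw p was 2e-05, the smallest 100000 draws can give, and the adjusted p was 0.00036. Gapdh2, a glycolytic enzyme gene, had the strongest peak of the list, 588, located 163 bp upstream of its start. Act5C, a cytoplasmic actin gene, had 294, RpL32 had 219 and RpL7 had 193, while Act42A and Gapdh1 had none. For 27 of the 28 genes a summit lay within 500 bp of a start of the gene. With only summits farther than 500 bp from any start, 1 gene of the list was bound against 3.86 expected (adjusted permutation p = 0.645). With only the 1527 strongest peaks, 12 were bound against 6.34 (adjusted permutation p = 0.197). The 5000 strongest ranked peaks outside the conservative list gave the call too, with 29 bound against 13.9 (adjusted permutation p = 0.00072). It was therefore not particular to the conservative peaks.

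Odorant, gustatory and ionotropic receptor genes, a control list for sensory neurons of larvae and adults, had 8 of 179 bound against 26.2 expected (adjusted permutation p = 0.00036). Gr93a had the strongest of these peaks, 226, and Ir94d the next, 116, while Gr10a and Gr10b had none. The call was not made with only summits away from starts, where 8 stood against 14.1 expected (adjusted permutation p = 0.53), or with the 5000 strongest ranked peaks outside the list, where 32 stood against 42.0 (adjusted permutation p = 0.305). Without replicate 1 the list had 3 bound against 18.2, a ratio of 0.165 in place of 0.305. Eggshell and yolk genes, the second control, had 0 of 13 bound against 1.34 expected (adjusted permutation p = 0.786). Even this count of 0 gave an unadjusted permutation p of 0.479, so the list could not pass as lower.

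The lists of neural genes did not pass. Neuroblast factors had 7 of 22 bound against 5.42 expected (adjusted permutation p = 0.792). Among them were brat, a translational repressor that limits neuroblast growth, with 475 in its intron at 2L 19165034 to 19165284, and grh, a late temporal factor, with 256. SoxN, a Sox gene of the neuroectoderm, had 214 and Myc, a growth regulator, had 167. The proneural gene ac and E(spl)mgamma-HLH, a Notch target, had none. Genes of asymmetric division had 8 of 17 bound against 4.05 (adjusted permutation p = 0.188). numb, an inhibitor of Notch inherited by 1 daughter cell, had 308, the apical polarity gene baz had 237 and cno had 211, while insc and l(2)gl had none. This list was called with no matching on territory length (8 against 2.48, adjusted permutation p = 0.0139) and with summits counted in the gene or within 2000 bp of it (10 against 4.29, adjusted permutation p = 0.0427). The temporal series of neuroblasts had 2 of 9 bound against 2.85 (adjusted permutation p = 1), grh and dan, and Kr and cas had none. Cell cycle genes had 6 of 15 against 2.52 (adjusted permutation p = 0.188), with CycB at 585, CycE at 176, trbl at 132 and Cdk1 at 126, and CycA and CycD unbound. Neuron differentiation genes had 5 of 21 against 5.61 (adjusted permutation p = 1), and elav, an RNA-binding protein gene of neurons, had 491 at X 523361 to 523620. sli, a midline guidance cue, had 135 and fne 106, while Appl and ChAT had none. Motor and interneuron factors had 6 of 16 against 4.62 (adjusted permutation p = 0.792), with zfh1 at 267 and vvl at 181, and Lim3 and ap unbound. Glial genes had 4 of 11 against 1.98 (adjusted permutation p = 0.517), with moody, a receptor gene of the blood-brain barrier, at 269 and Gli at 230, and Eaat1 and alrm unbound. Without replicate 1 cell cycle genes had 3 bound against 1.76 expected, asymmetric division genes 5 against 2.80 and the temporal series 1 against 1.95. Neuroblast factors had 6 against 3.71 there and 4 against 4.47 without replicate 2, where neuron differentiation genes had 2 against 4.65. None of these passed.

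Lists of other tissues and of patterning genes did not pass either. Neuroectoderm genes known to be repressed by Snail had 5 of 14 bound against 3.74 (adjusted permutation p = 0.792), with the FGF gene ths at 252, brk at 233, the BMP inhibitor gene sog at 175 and crb at 105, and with Delta and E(spl)m8-HLH unbound. The Notch pathway had 6 of 21 against 3.79 (adjusted permutation p = 0.624), with E(spl)m3-HLH at 241 and the ubiquitin ligase gene neur at 240, and Brd and Delta unbound. Mesoderm and muscle genes had 6 of 14 against 3.47 (adjusted permutation p = 0.517), with the heart gene tin at 305, kirre at 272 and sls at 263, and Act57B and Mhc unbound. Tracheal genes had 6 of 9 against 2.74 (adjusted permutation p = 0.188), with rib at 264 and stumps at 185, and btl and esg unbound. They were called with no matching on territory length (6 against 1.31, adjusted permutation p = 0.00492). Gap, pair-rule and segment polarity genes had 6 of 21 against 5.79 (adjusted permutation p = 1), with slp2 at 339, the Hedgehog receptor gene ptc at 254 and wg at 148, and Kr and en unbound. Hox genes had 4 of 8 against 2.60 (adjusted permutation p = 0.786), with Antp at 112.5, Abd-B at 96.9, abd-A at 78.0 and Ubx at 67.4, and Dfd and Scr unbound. Endoderm and fat body genes had 2 of 8 against 2.35 (adjusted permutation p = 1), Fas3 at 209 and fkh at 69.2, and GATAe and Ser had none. Without replicate 1 the Notch pathway had 3 bound against 2.64 expected and endoderm and fat body genes 1 against 1.61. Genes repressed by Snail had 5 against 2.56 there and 3 against 3.10 without replicate 2. Hox genes had 2 against 1.79 without replicate 1 and 2 against 2.17 without replicate 2. None of these passed.

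**Figure D2:**
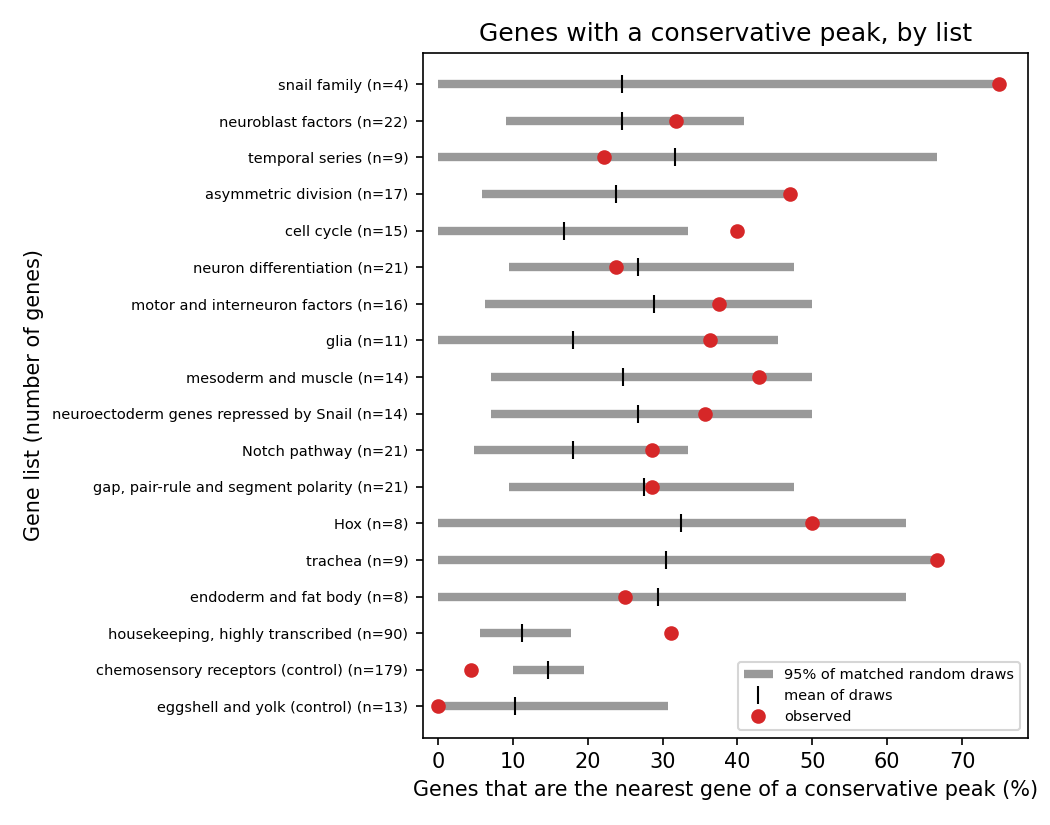
Percentage of the genes of each of 18 lists that were the nearest gene of a conservative peak (x axis), with the list and its number of genes on the y axis. Red points are observed, black ticks the mean and grey bars the central 95% of random draws matched on territory length; housekeeping genes stand at 31.1% and chemosensory receptors at 4.47%.

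The place of the peaks in the genome was compared with random placement on the same arms. Promoter regions were recovered more often and protein-coding exons less often. Of the 3045 summits, 1268 (41.6%, interval 39.9 to 43.4) lay within 500 bp of an annotated transcript start, against a mean of 13.6% (range 11.9 to 15.7) in 1000 placements. The p was 0.002, the smallest two-sided value the placements can give. Ranked peaks outside the conservative list had 15.2% there. The share was 26.1% within 200 bp and 52.4% within 1000 bp. Introns held 52.2% of the summits against 42.6% in random placements, intergenic sequence 36.9% against 30.5% and 5' UTRs 5.39% against 3.04%. Coding exons held 1.15% against 17.2% and 3' UTRs 1.31% against 4.92%. Non-coding exons held 2.99% against 1.73%.

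By chromosome arm, the X had more conservative peaks than its share of bases and chromosomes 4 and Y had fewer. The X held 617 peaks, 20.3% of peaks with 17.1% of bases, a ratio of 1.18 (exact binomial test, two-sided, adjusted over 7 arms, p = 1.58e-05). The ratio was 1.48 against the X share of the ranked peaks outside the list, 13.7%. Chromosome 4 held 4 peaks, a ratio of 0.135 (exact adjusted p = 3.23e-08), and the Y held 0 of 3045, which allows a share of up to 0.0985% against 2.49% of bases (exact adjusted p = 6.93e-33). Expected shares from bases take no account of copy number or mappable sequence, and neither was measured here. The chromosome 4 ratio was 0.287 without replicate 1 and 0.227 without replicate 2, and the list of replicate 1 held 2 peaks on the Y. Set against ranked peaks in place of bases, neither passed, with exact adjusted p of 0.827 for chromosome 4 and 0.738 for the Y. The Y share of those peaks was 0.0337%, so even a count of 0 could not pass as lower, and this comparison decides nothing for the Y. Arm 3L held 683 peaks, a ratio of 1.10 (exact adjusted p = 0.0114), but did not pass in the list of either replicate alone. Arms 2L, 2R and 3R had ratios of 1.04, 0.947 and 0.935 and did not pass. In both single-replicate lists 3R passed as lower, at 0.880 and 0.889, and 2L passed as higher, at 1.11 and 1.10 (exact adjusted p = 0.0464 without replicate 1 and 0.0479 without replicate 2). In the second list of both replicates 2R passed as lower, at 0.894, and against ranked peaks in place of bases 3R passed as lower, at 0.830, while 3L did not pass.

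Sequence at the summits was compared with sequence nearby, to ask whether the E-box bound by Snail-family proteins marked the peaks. It did not, in this window. CAGGTG lay within 50 bp of 62 of 3045 summits (2.04%, interval 1.59 to 2.60) against 129 (4.24%) of windows of the same width centred 500 bp downstream. The share was lower at summits (exact sign test, two-sided, adjusted over 11 motifs, p = 2.58e-06). The reversed control hexamer GTGGAC was lower too, 1.15% against 3.09% (exact adjusted p = 1.12e-06). Mean GC content was 32.2% at summits, 43.2% in windows 500 bp downstream and 43.9% in windows 500 bp upstream. A difference from these windows alone therefore cannot be told apart from an effect of base composition. Against shuffles of the summit windows that keep dinucleotides, the share of CAGGTG was 2.04% against 1.87% (exact adjusted p = 0.936). The GAGA motif was at 0.394% against 2.73% downstream (exact adjusted p = 3.53e-13), CAGCTG, an E-box of proneural proteins, at 2.73% against 4.83% (exact adjusted p = 4.79e-05), and CACGTG, the Myc-type E-box, at 0.722% against 1.41% (exact adjusted p = 0.0229). The Su(H)-type motif was at 0.624% against 1.41% (exact adjusted p = 0.00694). The Zelda-type (0.394%), Twist-type (3.71%), DRE (0.558%), M1BP-type (0.164%) and Grh-type (0.0328%) motifs did not pass against this window. Against the window 500 bp upstream the Zelda-type motif passed as lower, 0.394% against 0.952% (exact adjusted p = 0.0181), and the DRE as higher, 0.558% against 0.131% (exact adjusted p = 0.0132). The Grh-type motif passed as lower without replicate 1, 0.0558% against 0.502% (exact adjusted p = 0.0394).

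The setting decided some of these calls. The Su(H)-type call was not made in the second list of both replicates (0.751% against 1.21%, exact adjusted p = 0.145), with the 1527 strongest peaks (exact adjusted p = 0.414), without replicate 2 (0.662% against 1.06%, exact adjusted p = 0.314) or with 25 bp on each side (exact adjusted p = 0.16). The CACGTG call was not made with 100 bp (exact adjusted p = 0.0507) or 25 bp on each side (0.144), nor at distal summits (0.11), where the reversed control was not called either (0.0601). Without replicate 1 the ratio of summits to downstream windows was 0.182 for the reversed control and 0.286 for the Su(H)-type motif, in place of 0.372 and 0.442. Without replicate 2 it was 0.333 for CACGTG, in place of 0.512. Against shuffles no motif was lower by the test, with CACGTG at 0.722% against 0.821%, GAGA at 0.394% against 0.296% and the Su(H)-type motif at 0.624% against 0.525% (exact adjusted p = 0.936 for each). CAGCTG was above its shuffles, 2.73% against 1.15% (exact adjusted p = 0.000107). The DRE, a promoter motif bound by DREF, lay at 0.558% of summits against 0.131% of shuffles (exact adjusted p = 0.0396). Neither excess was particular to the conservative list. In ranked peaks outside it, CAGCTG was at 5.52% against 2.85% of shuffles (exact adjusted p = 8.02e-124). The DRE was at 0.207% there against 0.0656% of shuffles (exact adjusted p = 9.02e-11). Within 100 bp of conservative summits the DRE was at 2.27% against 0.558% downstream (exact adjusted p = 7.42e-08). Without replicate 1 the DRE was at 0.279% of summits against 0.335% downstream, a ratio of 0.833 in place of 2.12, so the direction turned, and it did not pass. With the 1527 strongest peaks the direction turned too, 0.262% against 0.393%. Among the 761 strongest peaks 9 (1.18%) had CAGGTG and among the 761 weakest 18 (2.37%), with a Fisher's exact p of 0.119. With windows of 100 bp on each side the order turned, 4.73% against 4.34% (Fisher's exact p = 0.806). Without weaker overlapping peaks it was 0.723% against 2.60% (Fisher's exact p = 0.01).

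Summits were AT-rich. Mean GC content of the 101 bp at the summit was 32.2% (SD 9.48 over 3045 peaks), against 43.5% and 44.4% in windows 200 bp to either side. In 2543 of 3045 peaks (83.5%, interval 82.2 to 84.8) the summit window had less GC than the mean of these flanks. Summit windows of the replicate 1 list had 31.0% and of the replicate 2 list 30.8%. Ranked peaks outside the conservative list had 45.9%. Among the 20 strongest peaks the summit of the Hr3 peak had the lowest GC, 18.8%, and that of the Ugalt peak the highest, 34.7%. The wor peak had 55.4%.

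**Figure D3:**
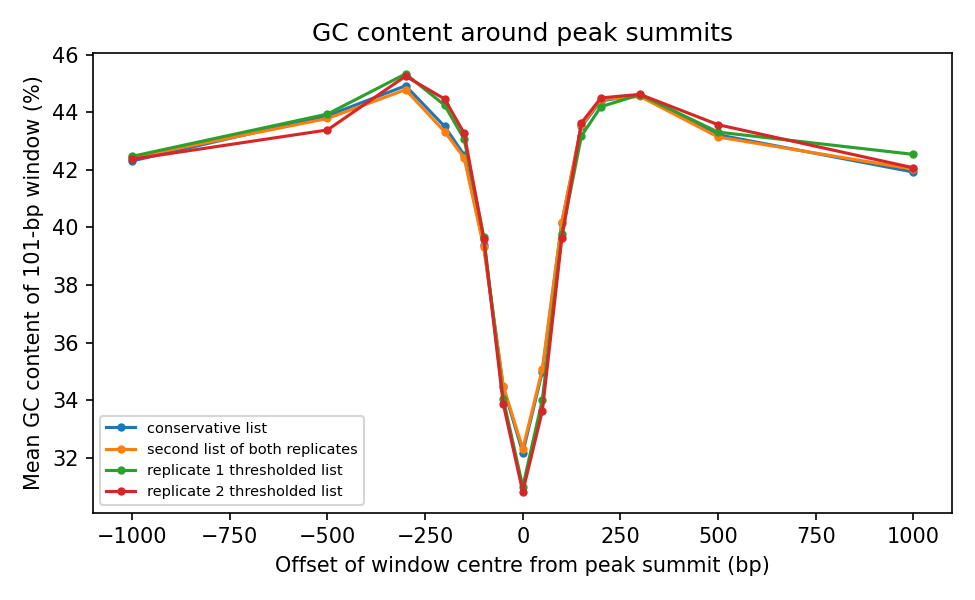
Mean GC content (%) of 101-bp windows on the y axis against the offset of the window centre from the peak summit in bp on the x axis, for the 4 thresholded lists. Each line falls to its lowest value at the summit, 32.2% in the conservative list, 31.0% in replicate 1 and 30.8% in replicate 2.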

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

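The shuffle test of the weaker ranked peaks was set before its result was seen; the ranges of rank were chosen after it.

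Weaker ranked peaks, used above as a background or as another peak set, held more Snail-type E-boxes at their summits than the conservative list: at ranks 10001 to 20000 of the ranked list by signal, 5.53% of summits had CAGGTG, with 4.47% in their dinucleotide-preserving shuffles, against 2.00% and 1.5% at ranks 1 to 1000, so the shuffles differed between the ranges too. The ratio to shuffles was 1.33 at ranks 1 to 1000 (exact adjusted p = 0.487), 1.5 at ranks 5001 to 10000 (5.94e-05), 1.24 at ranks 10001 to 20000 (0.00134) and 1.37 at ranks 20001 to 30000 (7.18e-06). At ranks 30001 to 40000 it was 1.19 (exact adjusted p = 0.0109). No call was made at ranks 1001 to 3000 (1.29, exact adjusted p = 0.412) or 3001 to 5000 (1.22, 0.271). Nor was one made in the weakest ranges, 40001 to 50000 (1.12, exact adjusted p = 0.113) and 50001 to 62469 (1.11, 0.113). Ranges up to rank 5000 held 1000 or 2000 peaks each and the others at least 5000, so calls cannot be compared between ranges. Over all 59424 ranked peaks outside the conservative list the share was 5.10% against 4.21% in shuffles, a ratio of 1.21 (interval 1.15 to 1.28, exact sign test p = 1.01e-13). A ratio above 1.2 with an exact sign test p under 0.05 had been set beforehand as excluding base composition, and the values met this rule. The margin was narrow, and the interval, on which the rule set no condition, includes 1.2. Base composition was therefore not called excluded. The reversed control hexamer GTGGAC had a ratio of 1.18 (1.11 to 1.25) to its own shuffles, so an excess of about this size was not limited to the Snail-type site, and no biological explanation was tested.

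In sequence outside the arms, 19 conservative peaks lay on unplaced contigs, which have no annotation here.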

How the results depend on the processing

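Results with overlapping weaker peaks left out, with ranked peaks as the peak set or the expected share, and with matching on promoter GC were chosen after seeing the data. The overlap of the replicates (62.0% to 85.2%), the share near starts (26.1% to 52.4%) and the excess on the X (ratios of 1.19 to 1.48) kept their direction and their side of the threshold under every alternative run. The correlation of signals was 0.798 to 0.827, always over peaks already selected for being alike in the replicates, so this range is no evidence of reproducibility. The reproducible peaks numbered 3081 in the second list. The single-replicate lists held 1801 to 2302. Depth limits are unknown because the files give no read counts.

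The number of lists bound more often than chance was 1 under most alternatives. It was 3 with no matching on territory length, 2 with summits in the gene or within 2000 bp, 0 with only summits over 500 bp from a start, and 0 with the 1527 strongest peaks. Fewer peaks enter the last 2 settings, but whether this cost the call was not tested. The 1793 peaks left without replicate 1 kept it, with 19 housekeeping genes against 7.01 (adjusted permutation p = 0.00054). Housekeeping genes then had 1 bound against 3.86 expected away from starts. With the 1527 strongest peaks 0 Hox genes and 0 Snail-family genes were bound, against 1.59 and 0.589. With no matching, endoderm and fat body genes had 2 against 1.17, neuron differentiation genes 5 against 3.06 and the temporal series 2 against 1.31, now above the expected count. With summits in the gene or within 2000 bp, segmentation genes had 2 against 5.46, motor and interneuron factors 4 against 4.33, neuroblast factors 5 against 5.51 and neuron differentiation genes 9 against 5.45. With the 5000 strongest ranked peaks outside the list, asymmetric division genes had 7 against 7.25, motor and interneuron factors 7 against 8.49, eggshell and yolk genes 2 against 1.82, endoderm and fat body genes 6 against 4.38, neuron differentiation genes 12 against 10.2 and the temporal series 6 against 5.39; chemosensory receptors had 32 against 42.0. None of the counts in these last 5 sentences passed its test.

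Without replicate 1 or 2, the ranges were 2 to 2 for Hox, 1 to 2 for endoderm and fat body, 4 to 6 for neuroblast factors, 3 to 5 for genes repressed by Snail, 2 to 4 for neuron differentiation, 0 to 2 for the Snail family, 3 to 5 for cell cycle and for the Notch pathway, 5 to 7 for asymmetric division, 1 to 2 for the temporal series and 3 to 6 for chemosensory receptors. These counts come from 1793 or 2266 peaks on the arms in place of 3045, so the expected counts were lower too. The ranges were 1.10 to 1.11 for the ratio on 2L, 1.07 to 1.08 on 3L and 0.880 to 0.889 on 3R. In both lists 2L and 3R gained a call and 3L lost its call. Motif shares were 0.279% (against 0.335%) to 0.485% (against 0.353%) for the DRE, 0.112% to 0.132% for the M1BP-type motif and 3.75% to 4.29% for the Twist-type E-box.

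Against ranked peaks in place of bases, the ratios were 0.923 on 2L, 1.03 on 3L, 0.830 on 3R, 0.736 on 4 and 0 on Y. Arm 3R gained a call and 3L, 4 and Y lost theirs, though on Y even a count of 0 could not pass as lower. 2R passed in the second list at 0.894. With the 1527 strongest peaks 3L no longer passed at 1.10 and 3R passed at 0.868.

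CAGGTG was at 2.04% against 1.87% in shuffles and at 5.10% against 4.04% in ranked peaks outside the list. Between the strongest and weakest peaks of the list it was 4.73% against 4.34% with 100 bp on each side, and 0.723% against 2.60% without overlapping weaker peaks (692 on each side), where the difference passed. Against shuffles, CAGCTG stood at 2.73%, GAGA at 0.394%, the Su(H)-type motif at 0.624% and the reversed control at 1.15%, each above its background, but only CAGCTG passed. In ranked peaks outside the list, CAGCTG (5.52%), GAGA (1.26%), CACGTG (1.42%), Su(H)-type (1.35%), Zelda-type (0.641%) and the reversed control (3.75%) were above the downstream window and DRE (0.207%), M1BP-type (0.0892%) and Twist-type (2.49%) below it; GAGA and M1BP-type did not pass. The DRE was at 0.262% in the 1527 strongest peaks, below its background of 0.393%, and the Zelda-type motif at 0.619% at distal summits, above 0.281%. What caused the changes between settings was not tested. Among the main values of the comparisons, under alternatives fixed beforehand 49 values kept direction and side of the threshold, 2 changed direction, 3 lost a call, 6 gained one and 4 moved. Under added alternatives these numbers were 18, 2, 3, 2 and 1. For single gene lists and motifs, 192 values kept both under the former, 25 changed direction, 11 lost a call and 8 gained one. Under added alternatives 58 kept both, 15 changed direction and 1 lost a call.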

Other observations

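The tests of Snail-type sites at AT-rich summits, of the IDR values of overlapping peaks and of the neighbourhoods of wor, sna and esg were chosen only after the results were seen, as were the ranges of rank and the GC values of gene lists.

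Among ranges of rank, promoters and the X had their highest shares in the strongest ranked peaks. Of ranks 1 to 1000, 54.1% of summits lay within 500 bp of a transcript start and 21.1% on the X. At ranks 1001 to 3000 these shares were 36.2% and 19.4%, and at ranks 5001 to 10000 they were 18.2% and 10.3%. The X share did not go on falling and was 11.8% at ranks 10001 to 20000, 14.5% at ranks 20001 to 30000 and 15.4% at ranks 30001 to 40000. The strongest peaks of the 28 bound housekeeping genes had a median summit GC of 44.1%, against 30.7% over all conservative peaks. They ran from 22.8% for RpL8 to 60.4% for RpL7, and no test or comparison with other promoter peaks was made. The bound Snail-family genes had a median of 54.5% and the bound tracheal genes 21.8%.

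The AT-rich summits of the conservative peaks were weighed against explanations from sequence. Base composition alone was argued against as the source of the share near starts. Of 2768 peaks, 42.0% lay within 500 bp of a transcript start. In 100 draws of windows with the same GC at centre and flanks the mean was 14.6% and the highest value 16.5%. This comparison cannot speak to the 1605 of these peaks that lay over 500 bp from any start. Promoter sequence was argued against for peaks away from starts, since 1605 peaks over 500 bp from any start had a median difference between summit and flanks of −15.3 percentage points (interval −15.8 to −14.4). A CAGGTG site as the general cause was argued against by its share of 2.04% of summits and a ratio of 1.09 to shuffles (0.766 to 1.54, exact sign test p = 0.707), though other sequences bound by Worniu were not tested. That ratio rests on 1 shuffle per window. Ratios to shuffles were 1.33 at ranks 1 to 1000 and 1.29 at ranks 1001 to 3000 of the ranked list, and neither passed. Recovery of accessible chromatin whatever the tagged protein, and Worniu brought to these sites by partner proteins, may both contribute, and neither was tested because no control immunoprecipitation is analysed here.

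Ranked peaks were dense around the tagged gene. Within 20000 bp of the wor start there were 45, at percentile 99.9 of 13968 protein-coding genes, with a median of 21 peaks per gene and a 95th percentile of 33, and the percentile was 99.87 in the ranked list of replicate 1 and 99.99 in that of replicate 2. By conservative peaks wor stood lower, at percentile 86.3. Extra copies of the locus on the transgene are a candidate explanation, but the test restates the pattern and the counting interval of the wor count, 32.8 to 60.2, includes 33, so it decides nothing. The 80 kb plotted around wor held only CG44869, wor and CG4161 as protein-coding genes, which argues against a gene-rich neighbourhood there. Gene density around other genes was not compared. An accessible neighbourhood shared by Snail-family genes cannot be told apart from extra copies of the locus. Here sna had 28 peaks and esg 33, and the higher of their percentiles, 94.8, lies within counting error of the bound of 95. In the single-replicate ranked lists, though, sna stood at 88.3 and 84.7 and esg at 67.5 and 70.9. The design has 1 group, so no biological explanation was tested.

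In the conservative list 280 peaks (9.14%) overlapped a stronger peak of the same list, with a median signal of 12.2 against 123.0 for the other 2784 and a median distance of 203 bp between summits. Of these, 95.7% had a −log10 global IDR within 0.01 of that of the stronger neighbour, and 2.17% of the 277 on arms had a summit within 100 bp in both replicates' ranked lists, against 95.5% of the other peaks.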
